A study of Arabidopsis thaliana with 8 samples.

How the data were processed

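Total RNA from whole plants was sequenced on 8 libraries, 1 for each of 4 lines at 0 and 75 mM NaCl. The authors deposited 1 table of raw counts per library, and per the submitters' processing notes reads were handled with TopHat2 2.0.5 and HTSeq on the TAIR10 build. The HTSeq version, the annotation release, the counting mode and whether strand was used are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and members of families with near-identical copies (such as LHCB1, the RBCS genes, COR15A and COR15B, KIN1 and KIN2) are uncertain. Each table held 32678 gene rows, 2 added rows named T31 and T43, and 5 summary rows. The summary rows took 2.49 to 2.60% of all reads in a library; they and the added rows were left out of library sizes and tests, the added rows being described on their own. Gene identifiers were matched to symbols through RefSeq assembly TAIR 10.1, which was used for names, product descriptions and gene neighbours only; 31912 identifiers (97.7%) matched.

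Gene reads per library ranged from 13007480 to 22820814 with a median of 21362251. CPM of genes are scaled by TMM factors, except where said otherwise, and those of the added rows by gene reads alone. A count of 0 allows up to 3 reads, which is 0.131 to 0.231 CPM in these libraries. Intervals for single counts are exact 95% Poisson intervals, and they and the floors cover counting error only. Reads on organelle-encoded genes ranged from 667 to 1213 CPM, and the 10 most abundant genes took 6.33 to 8.30% of the gene reads.

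Samples were grouped by line and salt level from their titles. There is 1 library per line and salt level, so lines served as the replicates, and the residual holds noise together with any difference in salt response between lines. The labels do not say whether separate plants or cultures stand behind the libraries, so p-values measure only the spread between these samples. The lines, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined.

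Tests used the deposited counts in R 4.3.3 with edgeR 4.0.16 (TMM factors, robust dispersion and robust quasi-likelihood fit) on 20585 genes reaching the CPM equivalent of 10 counts in the median library (0.468 CPM) in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The salt response was fitted with line as a block (3 residual degrees of freedom), and line replicates pair the 2 salt levels because both come from the same line. The 3F-VP16 lines were set against the control lines over both salt levels on counts summed per line (2 residual degrees of freedom), at 0 mM and at 75 mM within 1 fit of class by salt (4 residual degrees of freedom), and in their salt response as an interaction with line as a block (2 residual degrees of freedom). The biological coefficient of variation was 14.5% in the salt fit, 10.2% in it without T43-11, 13.9% in the line sums and 16.7% in the fit of class by salt. Fold changes are log2, and standard errors in edgeR are the absolute fold change divided by the square root of the F statistic. Single lines were compared without a test, as log2 ratios of CPM with a prior count of 2, on 12069 genes with a mean of at least 10 CPM, a gene counting as different at 2-fold. Pairs of libraries were compared by a chi-square per gene on genes with at least 20 reads in the pair, which compares those libraries and not the conditions.

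Gene lists fixed beforehand numbered 20 with 301 genes: abscisic acid and osmotic stress, cold, ion transport, aquaporins, reactive oxygen scavenging, jasmonate, salicylic acid and immunity, photosynthesis, phosphate starvation, iron deficiency, aliphatic glucosinolates, flavonoids, heat shock proteins, morning and evening clock genes, and markers of root, flower, seed storage, leaf senescence and reference genes. A list needed 4 tested members, which left 19; the seed storage list had 0 tested members and gave no result. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists. Medians of single libraries were set against 10000 random lists matched on mean expression. The overlap of T31-5 and T43-11, which share their controls, was compared with 100 simulations of unchanged lines. All lines, controls included, were drawn around the mean of the control lines at each salt level. The coefficient of variation was 10.2% for correlations and 10.2 and 16.7% for shared genes, of which the report gives the latter. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the descriptive steps.

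Named genes were chosen by rule: for the salt response and the class comparison, up to 8 genes in each direction with the highest fold change among those passing, with a mean of at least 5 CPM and the same direction in every line or library, and otherwise the 4 with the smallest p as not passing; for the other tests the 4 smallest p in each direction; up to 3 members of a list; and always RD29A, P5CS1, SOS1, HKT1 and NHX1. For single lines they were the 4 highest and 4 lowest mean ratios. Genes called only by another tool were singled out after their values were seen, and so was the use of this rule for the salt response without T43-11 and for T43-11 against the other lines.

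The tests were tested on simulated counts drawn from the real means and library sizes, with 200 of 20585 genes changed. At the coefficient of variation of the salt fit without T43-11 (10.2%), 92 and 99% of genes changed 2-fold and 4-fold were recovered for the salt response in 4 lines (5 false calls), 91 and 98% in 3 lines (13), 96 and 99% for the line sums (7), 93 and 96% at 75 mM (13), 62 and 90% for the interaction (7), and 41 and 93% for T43-11 against 3 lines (6). At the coefficient of variation of each comparison's own fit, these values were 87 and 100% in 4 lines (14.5%, 4 false calls), 78 and 100% for the line sums (13.9%, 9), 46 and 97% at 75 mM (16.7%, 5), 27 and 90% for the interaction (14.1%, 8), and 37 and 86% for T43-11 against 3 lines (10.1%, 2). These simulations hold no difference in response between lines of a class.

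Alternatives were DESeq2 1.42.0, size factors by the DESeq2 method (RLE) in edgeR, no filter on low counts, each line left out, the salt fit without the line block, limma-voom with line as a random effect, all 8 libraries taken as independent, fits on 1 salt level, prior counts of 0.5 and 8, mean CPM minimums of 2 and 50, and split controls. Chosen after the data were seen were the salt response without T43-11 as a result of its own with its alternatives, the sum of the empty vector line and T31-5 as 1 line, each line's salt response against the other lines, the class comparison at 75 mM without the T43-11 library at 0 mM, DESeq2 on the 75 mM libraries only, the gene list tests at 0 mM, at 75 mM, without T43-11 and for T43-11 against the other lines, and the ratio correlations at single salt levels. Reads, alignments, plant phenotypes and sequences of the constructs were not analysed here.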

Results

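RNA from whole Arabidopsis thaliana plants was sequenced in 4 lines, each at 0 and at 75 mM NaCl, with 1 library for each line and salt level. The lines were the wild type Col-0, an empty vector line and the lines T31-5 and T43-11. The empty vector line expressed only VP16, the activation domain of a herpes simplex virus transcription factor. By their labels, T31-5 and T43-11 expressed a 3F-VP16 fusion, an artificial transcription factor, and both were salt tolerant. Reads assigned to genes came to 21564640 and 13007480 in Col-0 at 0 and 75 mM, 18682236 and 21791327 in the empty vector line, 21741045 and 22820814 in T31-5, and 18664963 and 21159862 in T43-11. Between 22601 and 23479 genes had at least 1 read in a library, and 20585 genes entered the tests. The comparisons ask how the transcriptome responded to salt, and in what the 3F-VP16 lines differed from the control lines with and without salt.

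The tables carried 2 rows that are not Arabidopsis genes, T31 and T43, whose meaning is not given in the sources used here. T43 had 32.5 CPM (gene reads scaled to library size; 95% interval 29.9 to 35.2) in T43-11 at 0 mM and 33.6 (31.2 to 36.2) at 75 mM, 1 read in T31-5 at 75 mM, and 0 reads in the other 5 libraries. T31 had 26.8 CPM (24.5 to 29.2) and 27.7 CPM (25.5 to 30.1) in T43-11 at 0 and 75 mM. In T31-5 it had 4.88 CPM (3.99 to 5.90) and 2.94 CPM (2.28 to 3.73), and in the empty vector line 4.44 CPM (3.54 to 5.51) and 3.12 CPM (2.42 to 3.96). This row therefore did not tell T31-5 from the empty vector line. Col-0 had 0 reads on both rows, with 95% intervals that reach 0.171 CPM at 0 mM and 0.284 CPM at 75 mM. In what follows T31-5 stands for the libraries labelled T31-5.

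**Figure D1:**
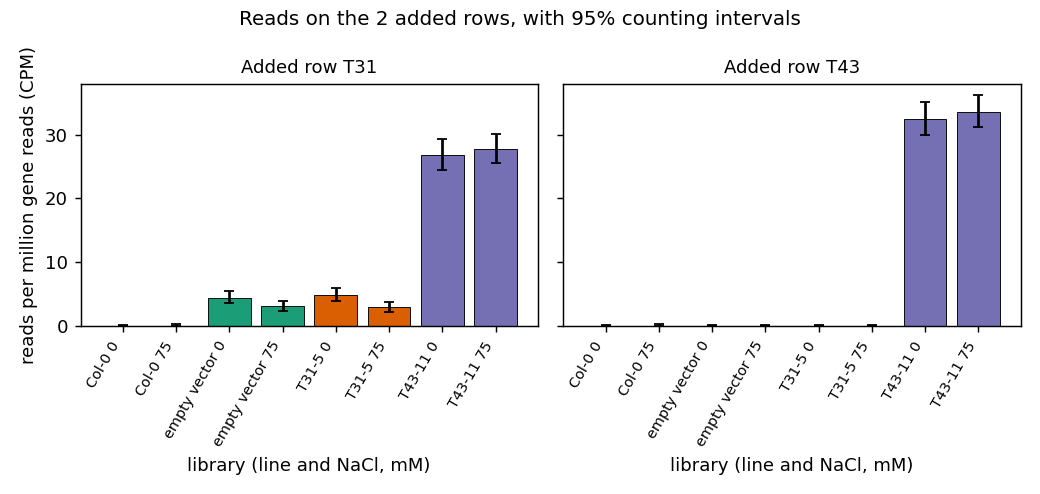
Reads on the added rows T31 (left) and T43 (right) in each of the 8 libraries, in CPM. Bars are single libraries and error bars are exact 95% Poisson intervals; T43 reached 32.5 and 33.6 CPM in the T43-11 libraries, and T31 was between 2.94 and 4.88 CPM in the T31-5 and empty vector libraries.

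In single lines, stress genes were higher and a clock gene lower with salt in Col-0, the empty vector line and T31-5, while in T43-11 these genes stood near the salt-treated level at both 0 and 75 mM. RD29A (AT5G52310), a gene induced by drought, salt and abscisic acid, went from 4.88 to 34.7 CPM in Col-0, from 4.56 to 39.5 CPM in the empty vector line and from 5.43 to 33.6 CPM in T31-5. In T43-11 it was at 58.8 CPM at 0 mM and 52.7 CPM at 75 mM. COR15A (AT2G42540), which encodes a chloroplast protein of cold acclimation, was at 1.34, 1.39 and 1.14 CPM without salt in Col-0, the empty vector line and T31-5 and at 44.6 CPM in T43-11. LHY (AT1G01060), a morning gene of the circadian clock, had 388, 269 and 277 CPM without salt in those 3 lines and 60.3 CPM in T43-11. Of 12069 genes with a mean of at least 10 CPM, 398 were at least 2-fold higher and 301 at least 2-fold lower with salt in Col-0. These counts were 287 and 192 in the empty vector line, 237 and 190 in T31-5, and 0 and 0 in T43-11. Each of these is 1 library against 1, with no replicate check.

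The 2 libraries of T43-11 were nearly equal and lay with the 75 mM libraries of the other lines. On the first principal component (55.4% of the variance) Col-0, the empty vector line and T31-5 were at -62.0, -45.0 and -44.6 without salt and at 11.4, 32.5 and 32.0 with salt, and T43-11 was at 37.4 and 38.4. The mean chi-square per gene between the libraries of a line, which sampling noise alone would put at 1, was 63.3 in Col-0, 50.5 in the empty vector line, 50.6 in T31-5 and 1.42 in T43-11. A second close pair was the empty vector line and T31-5 at 0 mM, with 1.44 and 1 gene at least 2-fold apart. Both pairs differed by more than sampling noise, and their libraries were kept apart. Across genes, which are not independent replicates, the log2 salt response of Col-0 had a correlation of 0.585 with the empty vector line and 0.533 with T31-5. The responses of the empty vector line and T31-5 had 0.761, which their close 0 mM libraries may raise. The response of T43-11 had 0.03 with each of these lines.

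**Figure D2:**
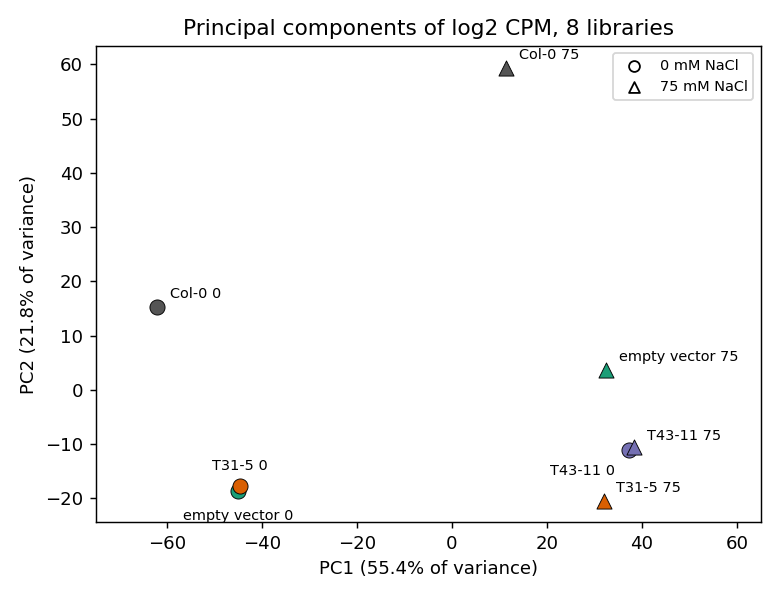
Principal components of log2 CPM for the 8 libraries, with the share of variance on each axis; colours are lines, circles 0 mM and triangles 75 mM NaCl. Both T43-11 libraries, at 37.4 and 38.4 on the first component, lie beside the 75 mM libraries of the empty vector line (32.5) and T31-5 (32.0), and the empty vector and T31-5 libraries at 0 mM overlap.

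**Figure D3:**
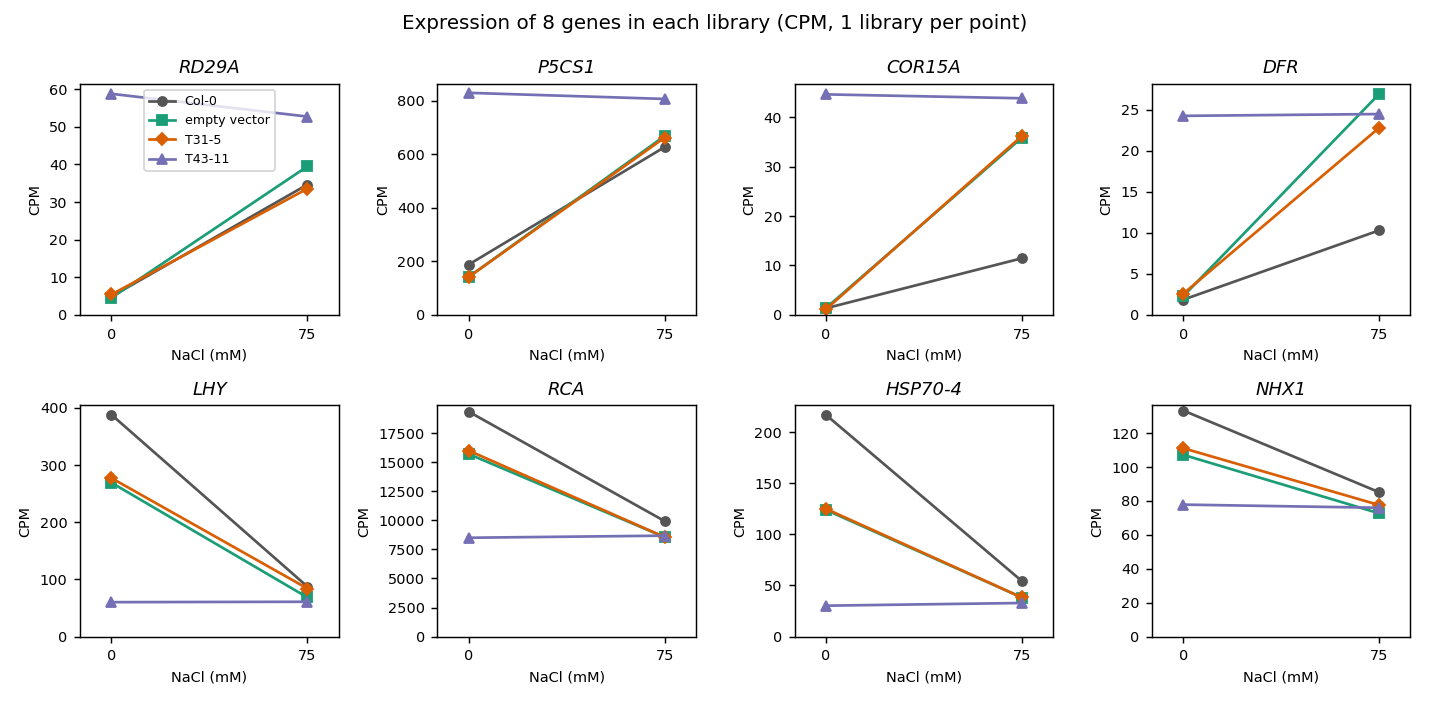
CPM of 8 genes against NaCl in mM, 1 library per point and 1 colour per line. RD29A was at 58.8 and 52.7 CPM in T43-11, and rose from 4.88 to 34.7 CPM in Col-0; LHY was at 60.3 and 61.0 CPM in T43-11, against 388 and 87.5 CPM in Col-0.

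Across all 4 lines no gene passed the test of the salt response at an adjusted p of 0.05 (edgeR quasi-likelihood test with line as a block, smallest adjusted p = 0.119). At an unadjusted p under 0.05 there were 6006 genes, 3135 of them higher and 2871 lower with salt. These counts were 2822 and 3183 with RLE size factors and 2118 and 2454 in DESeq2, so the direction with more genes depended on the method. The total ranged from 2246 without the empty vector line to 8770 without T43-11. At an adjusted p of 0.05 DESeq2 with the same design called 774 genes higher and 1017 lower. Among genes with the smallest p that moved alike in the 4 lines, NIT3 (AT3G44320), a nitrilase, had a log2 fold change of 0.89 ± 0.16 (SE), GDPD5 0.49, MAG1 0.45 and UNE18 0.47. On the lower side RTFL16 had -0.77, AT2G43140 -1.03, AT5G02540 -1.35 and the chloroplast gene ATCG00280 -0.99 (edgeR adjusted p = 0.119 for each). RD29A had 2.04 ± 0.58, P5CS1 (AT2G39800), the rate-limiting enzyme of proline synthesis, 1.57 ± 0.40, the sodium/proton antiporter gene SOS1 (AT2G01980) 0.33, the vacuolar antiporter gene NHX1 (AT5G27150) -0.44 and the sodium transporter gene HKT1 (AT4G10310) -0.42, none of which passed. Adjusted over the list alone, 11 genes of the abscisic acid and osmotic stress list rose and 2 fell, 8 cold-regulated genes rose and 7 heat shock genes fell. In the clock lists 1 morning gene rose and 4 fell, and 5 evening genes rose. Risers and fallers were 7 and 3 for jasmonate, 5 and 3 for reactive oxygen scavenging, 3 and 1 for flavonoids and 2 and 3 for ion transport. They were 2 and 0 for phosphate starvation, 0 and 2 for flower markers and 0 and 1 for leaf senescence. Over all genes the count was 0 for every list. Set tests called 5 lists higher and 4 lower with the preset correlation, and 0 with an estimated one. Leaving out T43-11 raised the count of passing genes to 2970 higher and 3172 lower, while it stayed at 0 without each of the other 3 lines.

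Without T43-11, in Col-0, the empty vector line and T31-5, salt raised 2970 and lowered 3172 of 20585 genes (edgeR, adjusted p of 0.05), and giving this fit an account of its own was decided after the data were seen. Among passing genes with a mean of at least 5 CPM and the same direction in the 3 lines, the largest rises were in RNS1 (AT2G02990), a ribonuclease, at 4.98 ± 0.40 log2 (adjusted p = 0.00095), the thioredoxin gene TH8 at 4.67 ± 0.23, COR15B at 4.50 ± 0.29 and the small peptide gene RTFL21 at 4.49 ± 0.32. They were followed by the acetyltransferase gene NATA1 at 4.35 ± 0.75, COR15A at 4.33 ± 0.35, JRG21 at 3.90 ± 0.67 and AT3G59930 at 3.83 ± 0.25. By the same rule the largest falls were in the cytochrome P450 gene CYP71B22 (AT3G26200) at -3.97 ± 0.18 (adjusted p = 0.000301), AT1G13650 at -3.02 ± 0.45 and AT3G16670 at -2.75 ± 0.39. Next came the nicotianamine synthase gene NAS3 at -2.59 ± 0.29, AT3G49160 at -2.44 ± 0.18, AT3G06145 at -2.33 ± 0.14, the phloem lectin gene PP2-A5 at -2.28 ± 0.42 and GDPD2 at -2.26 ± 0.23. RD29A rose by 2.83 ± 0.11 and P5CS1 by 2.05 ± 0.11. SOS1 rose by 0.40 ± 0.08 (adjusted p = 0.0105), NHX1 fell by 0.59 ± 0.06 (adjusted p = 0.00109) and HKT1, at -0.60 ± 0.20, did not pass (adjusted p = 0.0609). The count depended on single lines, with 3898 higher and 4044 lower without Col-0, 828 and 1228 without the empty vector line, and 1478 and 1734 without T31-5. It was 1215 and 1563 with the empty vector line and T31-5 summed as 1 line.

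In the lists of abscisic acid and osmotic stress, cold, flavonoid and iron deficiency genes, more members rose than fell in this 3-line fit. Of 30 tested genes of the abscisic acid and osmotic stress list 13 rose, 4 fell and 13 did not pass (14 and 5 adjusted over the list alone), with RD20 at 1.92 and RD22 at 1.24 among the risers. Of 12 cold-regulated genes 9 rose and 3 did not pass (9 and 0 adjusted over the list alone), KIN1 at 2.55. COR15A and COR15B, like other near-identical neighbours, can share reads. Of 12 flavonoid and anthocyanin genes 6 rose, 1 fell and 5 did not pass (6 and 3 adjusted over the list alone). DFR at 3.08, TT19 at 3.30 and UF3GT at 3.04, which act late in anthocyanin synthesis and transport, were among the risers. Of 14 iron deficiency genes 4 rose and 10 did not pass (4 and 0 adjusted over the list alone), led by the transcription factor genes BHLH100 at 3.52 and BHLH101 at 1.57 and by BTS at 0.89. The iron list had a median of 0.97 in Col-0, 0.98 in the empty vector line and only 0.13 in T31-5. The set test called these 4 lists higher with a preset correlation of 0.01 (adjusted p = 5.96e-08, 2.54e-10, 0.00298 and 0.000294), and none with an estimated one (adjusted p = 0.228, 0.198, 0.633 and 0.633 with an estimated correlation).

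Most photosynthesis and heat shock genes fell, and so did most morning clock genes. Of 26 photosynthesis genes 24 fell and 2 rose, the same counts as adjusted over the list alone. Among random lists matched on expression their median lay at percentile 0.04 in Col-0, 0.53 in the empty vector line and 6.52 in T31-5. Heat shock and morning clock genes lay at percentile 0.0 in each of these lines. The Rubisco small subunit gene RBCS2B was at -1.09, the Rubisco activase gene RCA at -0.93 and PORB, an enzyme of chlorophyll synthesis, at 1.94. Of 10 heat shock genes 8 fell and 2 did not pass (0 and 8 adjusted over the list alone), HSP70-4 at -1.82, HSP90.1 at -1.52 and HSFA7A at -1.02. The morning clock genes LHY, RVE8 and CCA1 fell by 1.96, 1.47 and 1.2, with 4 of 5 members falling and 1 rising (1 and 4 adjusted over the list alone). Of 9 evening genes 5 rose and 4 did not pass (6 and 0 adjusted over the list alone), GI at 0.76, PRR5 at 1.63 and ELF3 at 0.64. The time of harvest is not given in the sources used here. These 4 lists were called with the preset correlation (adjusted p = 1.26e-10, 4.16e-10, 8.89e-09 and 0.000441), and none with an estimated one (adjusted p = 0.623, 0.198, 0.4 and 0.282 with an estimated correlation).

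The other lists were not called in the 3-line fit with either correlation. Of 23 genes of sodium, potassium and proton transport 5 rose, 4 fell and 14 did not pass (6 and 5 adjusted over the list alone). The guard cell potassium channel gene KAT1 was at -1.23 and the antiporter gene NHX6 at 0.79. Of 19 aquaporins 2 rose and 2 fell, also when adjusted over the list alone, PIP2;5 at 1.14, TIP1;1 at 0.35 and TIP2;1 at -0.24 among them. Of 14 genes of reactive oxygen scavenging 5 rose and 4 fell (5 and 5 adjusted over the list alone), with the catalase gene CAT2 (AT4G35090) at -0.79, the iron superoxide dismutase gene FSD1 at -0.81 and FSD2 at 0.82. Of 20 jasmonate genes 6 rose and 4 fell, also when adjusted over the list alone, the synthesis genes AOS at 0.88 and AOC2 at 1.2 and the repressor gene JAZ6 at -0.78. The jasmonate list had a median of 0.77 in Col-0, 0.55 in the empty vector line and -0.05 in T31-5. Of 16 genes of salicylic acid and immune response only FMO1 rose, at 1.62 (1 and 0 adjusted over the list alone), and PR5 had -1.68 (adjusted p = 0.132). In that list the median was -0.08 and the set test pointed higher (adjusted p = 0.718). All 16 had a ratio above 0 in Col-0, where their median was 0.81, against -0.40 in the empty vector line and -0.37 in T31-5. The control lines already differed without salt. The empty vector line over Col-0 had a median of 1.51 at 0 mM, with all 16 higher, and of -0.27 at 75 mM. T31-5 adds little here, because its 0 mM library was close to that of the empty vector line.

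Among the remaining lists, 3 of 10 phosphate starvation genes rose and 0 fell, also when adjusted over the list alone, PHT1;1 at 0.68, PHT1;4 at 0.91 and PS2 at 2.53. Of 12 aliphatic glucosinolate genes 2 rose and 3 fell (2 and 6 adjusted over the list alone), MAM1 at 0.35 and CYP79F1 at -0.43. Of 14 root markers 3 rose (3 adjusted over the list alone), the nitrate transporter gene NRT2.1 at 3.22, the beta-glucosidase gene PYK10 at 0.57 and the root hair regulator RHD6 at 0.98, while the median of the list was -0.54 in Col-0, 0.15 in the empty vector line and 0.93 in T31-5. Of 4 tested flower markers the floral identity genes AP1, at -3.97, and SEP3, at -1.40, fell (0 and 2 adjusted over the list alone). AP1 was at 0.1, 0.67 and 0.81 CPM at 0 mM in Col-0, the empty vector line and T31-5. At 75 mM it was at 0.0, 0.04 and 0.04 CPM, below the floor of 3 reads, so the size of its fall is uncertain. Of 11 leaf senescence genes PAO rose, at 0.38, and the NAC factor gene NAP fell, at -1.09 (0 and 1 adjusted over the list alone). Of 8 reference genes GAPC1 rose, at 0.27, and ACT2 fell, at -0.61 (1 and 1 adjusted over the list alone).

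**Figure D4:**
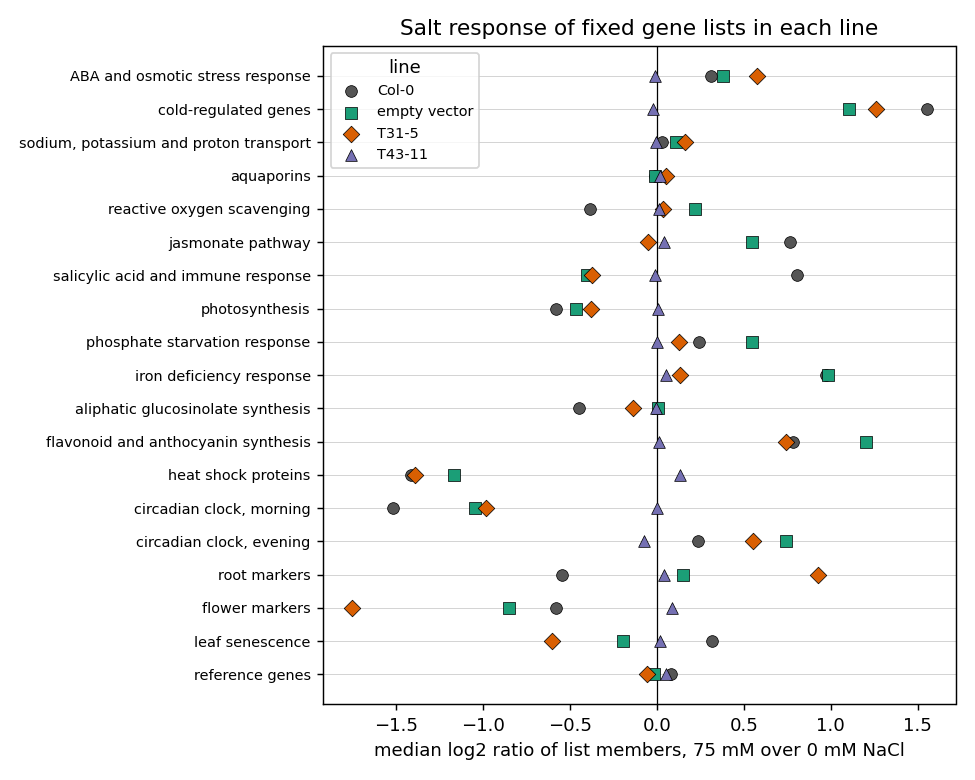
Median log2 ratio of the 75 mM over the 0 mM library for the members of 19 gene lists fixed beforehand, 1 point per list and line. The cold-regulated list was at 1.55 in Col-0, 1.11 in the empty vector line and 1.26 in T31-5 and at -0.02 in T43-11; heat shock genes were at -1.41, -1.16, -1.39 and 0.14.

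A test of the salt response of T43-11 against that of the other 3 lines was chosen after this line was seen to stand apart. It therefore restates that observation gene by gene. Of the other lines, the empty vector line and T31-5 had close libraries at 0 mM (mean chi-square per gene 1.44). They may not be separate replicates, so the spread in this test may be too small, and no fit of it with them summed was run. The log2 response of T43-11 was higher at 273 genes and lower at 227 (edgeR interaction term, 3927 genes at an unadjusted p under 0.05), with T43-11 as a single line, so that the spread comes from the other 3 lines alone. Among passing genes with a mean of at least 5 CPM the term was lowest for RNS1 at -5.10 ± 0.62 (adjusted p = 0.0311), TH8 at -4.75, RTFL21 at -4.61, COR15B at -4.45, COR15A at -4.39, AT3G59930 at -4.02, AT2G16660 at -3.84 and CORI3, a jasmonate-induced gene, at -3.50. It was highest for CYP71B22 at 4.06 ± 0.48 (adjusted p = 0.0286), AT3G49160 at 2.46, ABCG27 at 2.39, the guard cell factor gene MYB60 at 2.35, AT3G06145 at 2.35, AT2G34060 at 2.06, AT1G29720 at 2.03 and AT3G54510 at 2.02. For RD29A it was -3.01 ± 0.19 (adjusted p = 0.0181) and for P5CS1 -2.11, whereas SOS1 at -0.35, HKT1 at 0.68 and NHX1 at 0.54 did not pass (adjusted p = 0.258, 0.432 and 0.0733). The same test on each of the other lines called 0 genes, with 1437 (Col-0), 163 (empty vector) and 215 (T31-5) at an unadjusted p under 0.05, but T43-11 adds to the spread in those tests, so these counts are no contrast to its own. Without Col-0 the T43-11 term was higher at 1538 and lower at 1286 genes, without T31-5 at 123 and 192, and without the empty vector line at 0 and 1, AT2G16660.

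By list, the term was lower for 6 of 30 genes of abscisic acid and osmotic stress, RD20 at -1.90 among them (1 higher and 9 lower adjusted over the list alone). It was lower for 2 of 12 cold-regulated genes (0 and 8 adjusted over the list alone) and for 3 of 12 flavonoid genes (1 and 5), DFR at -3.09, UF3GT at -3.65 and TT19 at -2.91. Of 9 evening clock genes 2 were lower (0 and 3), GI at -0.85 and PRR5 at -1.80. Of 26 photosynthesis genes 4 were higher and 1 lower (20 and 2), RCA at 0.94 and PORB at -1.96. Of 10 heat shock genes 2 were higher (5 and 0), HSP70-4 at 1.92 among them, and so were 2 of 5 morning clock genes (4 and 1), LHY at 1.96 and RVE8 at 1.46. Of 14 iron deficiency genes 1 was lower (0 and 1), BHLH100 at -3.38. Single genes of lists that were not called, AOS at -1.01, CAT2 at 0.76 and FSD1 at 0.83, passed as well. The 8 lists given before these, 3 higher and 5 lower, were called with the preset correlation and 0 with an estimated one (adjusted p = 0.317, 0.218, 0.661, 0.434, 0.661, 0.218, 0.487 and 0.695 with an estimated correlation, in the order given).

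The salt response did not differ detectably between the 3F-VP16 lines and the control lines taken as classes. The genes with the smallest p were MLP329, with a difference of log2 responses of 1.05, the dehydrin gene RAB18 (AT5G66400) with 1.24, the chloroplast gene ATCG00920 with 0.72 and the peroxidase gene AT1G05250 with 1.55. On the lower side they were WRKY18 (-1.51), PHI-1 (-1.16), DREB26 (-1.06) and AT3G12900 (-2.09). The edgeR adjusted p was 0.968 for all 8. edgeR called 0 genes, with 745 at an unadjusted p under 0.05 (260 higher and 485 lower). DESeq2 called 2, TI1 at -2.34 and AT4G36700 at -4.72, both singled out after their values were seen. Without T31-5 the test called 123 genes higher and 192 lower, which is T43-11 alone against the control lines, with the spread of the control lines only.

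Over both salt levels no gene passed between the 3F-VP16 lines and the control lines. With the libraries of each line summed, 2 lines against 2, named genes are those with the smallest p that lay beyond both controls in each 3F-VP16 library. RD29B, an abscisic acid response gene, had 1.44 ± 0.20, the peroxidase gene AT1G05240 1.29 ± 0.18, the extensin gene EXT13 1.73 ± 0.26 and the peroxidase gene AT5G17820 0.71 (edgeR adjusted p = 0.7 for each). AT3G12900, which encodes an enzyme of coumarin synthesis under iron deficiency, had -1.34 ± 0.16, the light stress gene ELIP1 -1.14, ASPGB1 -0.82 and AT4G23680 -0.63 (adjusted p = 0.7 for each). RD29A had 0.89, P5CS1 0.63, SOS1 0.03, HKT1 -0.06 and NHX1 -0.25, which did not pass either. At an unadjusted p under 0.05 edgeR had 845 genes (511 higher and 334 lower), a count that moved with each line left out. DESeq2 had 456 higher and 523 lower there, so the direction with more genes depended on the method. At an adjusted p of 0.05 edgeR called 0 genes, limma-voom 0, and DESeq2 25 higher and 3 lower. The DESeq2 calls, read after the data were seen, included RHS12 at 2.1, XTH14 at 1.73, PRP3 at 1.73, AGP3 at 1.69, RHS19 at 1.69, EXT10 at 1.61 and EXT12 at 1.55 on the higher side. On the lower side they were AT3G12900, ELIP2 at -1.66 and AT5G35935 at -2.50. Without the empty vector line, with Col-0 as the only control line, edgeR called AT3G01345, at -9.15, and ELIP2, at -2.12.

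Among the lists in that comparison, root markers were called higher (median 0.77, adjusted p = 4.18e-09 with the preset correlation and adjusted p = 0.396 with an estimated correlation) and so were cold-regulated genes (0.74, 2.9e-05 and adjusted p = 0.398 with an estimated correlation). Iron deficiency genes (-0.29, 1.36e-07 and adjusted p = 0.396 with an estimated correlation) and heat shock genes (-1.11, 1.21e-06 and adjusted p = 0.396 with an estimated correlation) were called lower. The values for cold-regulated and heat shock genes were furthest from 0 in the T43-11 library at 0 mM, which lay with the 75 mM libraries, at 1.83 and -1.98 over the controls, against 0.67 and -0.56 in T43-11 at 75 mM, 0.06 and -0.36 in T31-5 at 0 mM and 0.26 and -0.50 at 75 mM. PRP3 at 1.73, LRX1 at 1.63 and HSFA2 at -1.71 were members with small p. In all, 4 lists were called higher and 7 lower with the preset correlation and 0 with an estimated one, and 0 members passed over all genes. Adjusted over the list alone, RD29B of the abscisic acid and osmotic stress list rose and 0 genes of the other lists passed. The control lines differed from each other in these lists too. The empty vector line over Col-0 had a median of 0.32 at 0 mM and 1.04 at 75 mM for root markers and of -0.90 and -0.62 for heat shock genes.

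At 0 mM the genes with the smallest p were, on the higher side, AIR1 (1.63 ± 0.38), ORP1A (0.74), AT1G29240 (0.78) and AT4G12545 (1.23). On the lower side they were AT4G10620 (-0.59), AT5G24000 (-0.67), AT3G52920 (-0.47) and AT3G48460 (-0.78), and the adjusted p was 0.587 for all 8. At an unadjusted p under 0.05 edgeR had 1093 genes (661 higher and 432 lower), and 242 on the 0 mM libraries alone. There were fewer such genes without Col-0 or without T43-11, and more without either of the other lines. At an adjusted p of 0.05 edgeR called 0 genes and DESeq2 0. Without T31-5 the counts were 132 higher and 41 lower, for T43-11 alone against the control lines. The lines stood apart here. Over the controls, T31-5 had a median of 0.06 for cold-regulated genes, -0.36 for heat shock genes, -0.20 for morning and 0.12 for evening clock genes and -0.03 for root markers. T43-11 had 1.83, -1.98, -1.40, 1.14 and 1.16. With the preset correlation, in list tests at this level chosen after the data were seen, 5 lists were called higher and 4 lower, and 0 with an estimated one.

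At 75 mM both 3F-VP16 lines lay on the same side of the controls for root, iron and jasmonate genes, with no gene passing in the planned fit. RD29B had 2.11 ± 0.41, AT1G05240 1.81, MLP329 1.04 ± 0.18 and AT5G14330 0.97 on the higher side (edgeR adjusted p = 0.999). On the lower side AT3G12900 had -2.33 ± 0.25 (adjusted p = 0.435), CYP82C4, another gene of iron-dependent coumarin synthesis, -1.04, GSTL1 -0.75 and the jasmonate synthesis gene AOC1 -0.93 (adjusted p = 0.999). The iron list had a median of -0.67, with BHLH38 at -1.95, BHLH39 at -1.38 and the iron transporter gene IRT1 at -0.59. Of its 14 members 10 fell when adjusted over the list alone and 0 over all genes (set test adjusted p = 9.45e-19 with the preset correlation, adjusted p = 0.0842 with an estimated correlation). The jasmonate list had -0.37, with JAZ10 at -1.06 and LOX3 at -0.63, and 3 of 20 members fell when adjusted over the list alone (adjusted p = 6.6e-08, and adjusted p = 0.0842 with an estimated correlation). Root markers had 0.99, with the proline-rich wall gene PRP3 at 2.2, the root hair gene COBL9 at 1.58 and the Casparian strip gene CASP2 at 1.04 (adjusted p = 1.83e-10, and adjusted p = 0.275 with an estimated correlation). Phosphate starvation genes had -0.55, SPX1 at -0.86 (adjusted p = 0.000289, and adjusted p = 0.275 with an estimated correlation), and 0 members of either list passed over the list alone. Photosynthesis genes were called higher (median 0.12, adjusted p = 0.00574, and adjusted p = 0.642 with an estimated correlation) and leaf senescence genes lower (-0.31, adjusted p = 0.00167, and adjusted p = 0.275 with an estimated correlation). The empty vector line over Col-0 had 0.105 for photosynthesis and -0.422 for leaf senescence genes at 75 mM. The list tests at this level were chosen after the data were seen.

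edgeR called 0 genes at 75 mM, with 731 at an unadjusted p under 0.05 (359 higher and 372 lower), also 0 on the 75 mM libraries alone and 0 without the T43-11 library at 0 mM. DESeq2 called 9 higher, among them AT1G05250 at 2.12, EXT12 at 2.02 and EXT13 at 2.21, and 9 lower, among them AT3G12900, BHLH38, WRKY18 at -1.50 and ELIP2 at -2.16. On the 75 mM libraries alone it called 30 higher and 48 lower, in a fit chosen after the data were seen. Root markers had a median of 0.98 in T31-5 and 1.13 in T43-11 over both controls, where the empty vector line itself had 1.04 over Col-0; for iron genes these values were -0.86, -0.59 and -0.35, for jasmonate genes -0.28, -0.37 and -0.17, and for phosphate starvation genes -0.65, -0.42 and -0.37. With the preset correlation 2 lists were called higher and 5 lower, and 0 with an estimated one. On the 75 mM libraries alone these counts were 6 and 5, and 0 with an estimated one. Adjusted over the list alone in that fit, 3 root markers rose, 1 phosphate starvation gene rose and 4 fell, 9 jasmonate genes fell and 11 iron deficiency genes fell. In the list of abscisic acid and osmotic stress 2 genes rose and 3 fell, and 2 leaf senescence genes and 1 aliphatic glucosinolate gene fell.

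**Figure D5:**
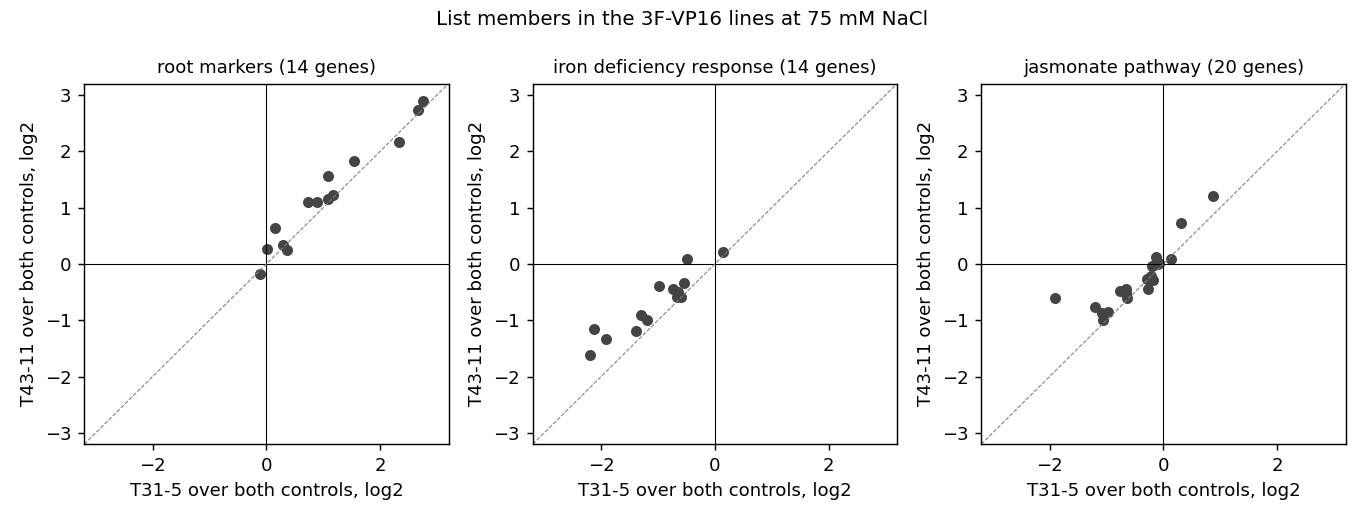
Log2 ratio over the mean of both control lines at 75 mM NaCl in T31-5 (horizontal) and T43-11 (vertical) for members of 3 fixed lists, 1 point per gene; the dashed line marks equal ratios. Root markers had medians of 0.98 and 1.13 in the 2 lines and iron deficiency genes -0.86 and -0.59; both lines share their control libraries.

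Taken as single lines over both salt levels, T31-5 and T43-11 had few genes at least 2-fold from the controls at both levels. In T31-5, 4 genes were higher, AT3G53980 at 1.24 and 2.0 (0 and 75 mM), AT4G25580 at 1.70 and 1.96, AT3G48410 at 1.16 and 2.03 and GASA6 at 1.19 and 1.44, and 1 was lower, AT3G01345 at -5.54 and -4.49. At 0 mM the empty vector line stood near T31-5 at these genes and Col-0 apart from both, with AT3G53980 at 6.47, 30.8 and 33.7 CPM, AT4G25580 at 4.11, 38.4 and 41.4, AT3G48410 at 4.16, 22.7 and 21.8 and GASA6 at 39.4, 213 and 209 CPM in Col-0, the empty vector line and T31-5. AT3G01345 had 152 and 86.6 CPM in Col-0 and under 1 CPM in each transgenic library, so that it sets Col-0 apart from the 3 other lines. In T43-11, 20 were higher, with COR15A at 4.93 and 1.11, EXT10 at 1.73 and 2.65, HRGP1 at 2.1 and 1.94 and AT1G14250 at 2.88 and 1.12 leading. In the same line 4 were lower, AT3G01345 at -4.30 and -5.21, LEA3 at -2.67 and -1.09, ELIP2 at -1.15 and -1.72 and AT1G51820 at -1.13 and -1.02. The lines shared 0 of the higher genes and 1 of the lower ones, AT3G01345, where independent lists would share 0.01 and 0.0. At 75 mM alone they shared 26 of 60 and 35 higher genes and 13 of 62 and 14 lower genes. Independent lists would share 0.17 and 0.07. Unchanged lines simulated against shared controls that did not differ from each other, at a coefficient of variation of 16.7%, shared 0.19 and 0.05. At 0 mM they shared 7 of 20 and 351 higher and 1 of 1 and 301 lower genes, against 0.58 and 0.02 for independent lists and 0.13 and 0.17 for simulated lines. The independent lists leave out the shared controls, and the simulated lines leave out the effects and the difference between the control lines. The excess over either is therefore no measure of a shared effect. At 75 mM T31-5 lay at least 2-fold from Col-0 at 354 genes and from the empty vector line at 27. For T43-11 these counts were 262 and 9, so most genes shared at 75 mM were not 2-fold from the empty vector line in T43-11.

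Across genes, the ratios of T31-5 and T43-11 to the shared controls had a correlation of 0.525 over both levels, where unchanged lines simulated against the same controls gave 0.349, and a covariance of 0.0645 against a simulated 0.0132. With the controls split, so that each line had its own control line, the correlation was 0.214 and 0.203 (simulated 0.002). At single levels, a choice made after the data were seen, it was at 75 mM 0.761 (simulated 0.366; covariance 0.120 against 0.0266) and 0.317 and 0.351 with split controls (simulated 0.0), and at 0 mM 0.300 (simulated 0.333; covariance 0.0575 against 0.0259) and 0.00 and -0.01 with split controls (simulated 0.001). Part of the excess of the values with shared controls over the simulation may come from the shared controls. Each split control is a single library at a given level. At 0 mM the T31-5 and empty vector libraries were close (mean chi-square per gene 1.44), so the ratio of T31-5 to the empty vector line held little but noise there. In the other split T31-5 stood close to the control of T43-11. The split values at 0 mM, and those over both levels that include them, are therefore no clean comparison.

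The empty vector line differed from Col-0 by at least 2-fold in the same direction at both salt levels at 21 genes higher and 3 lower, of 12069. The highest were UMAMIT14 at 1.17 and 3.79 (0 and 75 mM), AT3G53980 at 2.23 and 1.55, GASA6 at 2.43 and 1.22 and JAL23 at 2.12 and 1.53. The lower genes were AT3G01345 at -8.12 and -6.61, AT3G44970 at -1.58 and -1.27 and the anion channel gene SLAH3 at -1.04 and -1.07. Each is 1 line against 1, with no replicate check; across genes the ratios at the 2 levels had a correlation of 0.212.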

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

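The tests of explanations and of other splits of the samples given here were all chosen after the results were seen. T43-11 was seen to stand apart first, and a test of its salt response against that of the other 3 lines, in which it is a single line, then called 273 genes higher and 227 lower (0 and 1 without the empty vector line, 123 and 192 without T31-5, 1538 and 1286 without Col-0). Reads on the added rows, which enter no comparison, lay above the Col-0 controls: row T31 had 4.44 and 3.12 CPM in the empty vector line at 0 and 75 mM, 4.88 and 2.94 CPM in T31-5 and 26.8 and 27.7 CPM in T43-11, and row T43 had 32.5 and 33.6 CPM in T43-11.

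The T43-11 library at 0 mM lay with the 75 mM libraries, with RD29A and COR15A high and LHY low. A library of another line is argued against by row T43, at 32.5 CPM there and at 1 read or none in the other lines. For an exchange of the 0 and 75 mM labels of T43-11, its 75 mM library was set against T31-5. It lay 522 genes (at least 2-fold) from the T31-5 library at 0 mM and 6 from that at 75 mM, so neither T43-11 library looks untreated. This argues against an exchange only if untreated T43-11 plants resemble untreated T31-5 plants. Still open are salt-treated T43-11 material under the 0 mM label and, as a biological hypothesis, a state of this 3F-VP16 line that resembles the salt response without salt. Both allow close T43-11 libraries, and the 2 cannot be told apart because the line has 1 library per salt level. How far separate samples of 1 line and salt level differ is unknown here, so their mean chi-square of 1.42 does not decide. Besides the empty vector and T31-5 pair at 0 mM, the closest other libraries, T31-5 at 75 mM and T43-11 at 0 mM, had 4.36.

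The empty vector and T31-5 libraries at 0 mM differed by little more than sampling noise, at a mean chi-square per gene of 1.44 and 1 gene at least 2-fold apart. A single library under both labels that differs by sampling alone is argued against, since this would give 1. The value cannot exclude 1 library or RNA sequenced in separate runs, because any difference between runs would also raise it above 1. Plants or RNA of 1 line under both labels, or a construct with no detectable effect without salt, may each give this closeness. Row T31 does not part them, at 4.88 CPM (3.99 to 5.90) in T31-5 against 4.44 CPM (3.54 to 5.51) in the empty vector line, and cannot do so because it does not part these lines at 75 mM either. At 75 mM the same lines had a mean chi-square per gene of 7.69 and 27 genes at least 2-fold apart.

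Root markers were higher in both 3F-VP16 lines than in the controls at 75 mM. A larger share of root in the samples stays open: the median of the root hair members exceeded that of the other root members by at least 0.67 log2 in both lines and against either control set, but the quartile range of single members was wider in 3 of these 4 cases (0.75 for that value; 0.70 against 0.93 in T43-11 over the empty vector line), and some of the others, such as PYK10 and SCR, are abundant in these whole plants. Photosynthesis genes, at 0.09 in T31-5 and 0.16 in T43-11 over both controls, run against a larger root share. Leaf senescence genes, at -0.48 and -0.22, run with it. The empty vector line over Col-0 had -0.422 for leaf senescence and 0.105 for photosynthesis genes, so these lists differed between the control lines too. Leaf transcripts are also so abundant in whole plants that they would hide a small change of share. A difference between the control lines stays open too, because the empty vector line had a median of 1.04 over Col-0 and the 3F-VP16 lines only 0.45 and 0.69 over the empty vector line alone. An effect of the 3F-VP16 fusion on root hair genes is a hypothesis that 2 lines against 2 cannot settle.

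For the salt response in 4 lines the real split of the 8 libraries gave 0 genes, so each of the 32 splits that could be fitted, of 35, had to give as many (highest other 0), and the count says nothing about chance. For the 3 lines without T43-11 the real split gave 6142 genes and the highest of the others 0, and 10 splits are too few for a share under 0.05.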

How the results depend on the processing

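Alternatives chosen only after the results were seen were those of the salt response without T43-11, of T43-11 against the other lines, DESeq2 on the 75 mM libraries only, the fit without the T43-11 library at 0 mM, and the gene lists and ratio correlations at single salt levels. Under DESeq2 the count of genes higher and lower was 774 and 1017 for the salt response in 4 lines, 25 and 3 for the 3F-VP16 lines over both salt levels, 9 and 9 at 75 mM (30 and 48 on the 75 mM libraries only), 0 and 2 for the difference in salt response, and 1817 and 2236 for the salt response in 3 lines, where edgeR gave 0 in all but the last. Leaving out each line in turn gave 0 to 2970 higher and 0 to 3172 lower in the 4-line salt response (highest without T43-11), 0 to 2 lower over both levels (highest without the empty vector line), 0 to 132 higher and 0 to 41 lower at 0 mM and 0 to 123 higher and 0 to 192 lower for the difference in salt response (highest without T31-5, where T43-11 alone stands for the 3F-VP16 lines). It gave 828 to 3898 higher and 1228 to 4044 lower in the 3-line salt response (lowest without the empty vector line, highest without Col-0), and 0 to 1538 higher and 1 to 1286 lower for T43-11 against the other lines (lowest without the empty vector line, highest without Col-0). Summing the empty vector line and T31-5 as 1 line left 1215 and 1563 genes in the 3-line salt response. Without the replicate block of line the 4-line count stayed at 0 and the 3-line count was 2500 and 2477. With an estimated correlation 0 gene lists were called higher and 0 lower in each comparison. The correlation of T31-5 and T43-11 with split controls was 0.214 and 0.203 over both levels, 0.317 and 0.351 at 75 mM and 0.003 and -0.005 at 0 mM, and with shared controls and a prior count of 8 it was 0.776 at 75 mM. The empty vector line had 58 higher and 7 lower genes against Col-0 at a minimum mean of 2 CPM and 4 and 1 at 50 CPM, which test more and fewer genes. SOS1, 3F-VP16 lines against control lines over both salt levels, ranged from -0.05 (without the empty vector line) to 0.11, and HKT1 from -0.39 to 0.22 (without the empty vector line) and 0.21 (without T43-11). For the genes named in the text, 1238 of 1413 values kept their direction and side of the threshold, 99 lost and 73 gained it, and 3 turned direction. Size factors by the DESeq2 method and the fits without a filter moved 0 of the counts of genes passing at an adjusted p of 0.05 by over 1.5 times where they were run. Counts at an unadjusted p under 0.05 moved more. For the 3F-VP16 lines over both salt levels the lower genes went from 334 to 516 without a filter, which tested 25498 genes. Where a result changed, the cause was not tested.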

Other observations

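The hypoxia test below was written down before its values were seen, and the comparisons of gene families were chosen after the data were seen. A set of genes with known roles in the anaerobic response stood lower in Col-0 than in the 6 transgenic libraries, which are set against only 2 Col-0 libraries. Of 12069 genes, 16 were at least 2-fold higher and 2 at least 2-fold lower than in the Col-0 library of the same salt level in each of these libraries, and the 16 included the alcohol dehydrogenase gene ADH1 (mean log2 ratio 1.69), the pyruvate decarboxylase gene AT4G33070 (1.96), the haemoglobin gene HB1 (1.88) and the sucrose synthase gene SUS4 (1.98), along with UMAMIT14 (2.48), PORA (1.69) and FRO4 (1.74). ADH1 had 23.0 and 39.1 CPM in Col-0 at 0 and 75 mM, 52.3 and 122 CPM in the empty vector line, 52.5 and 137 CPM in T31-5 and 130 and 138 CPM in T43-11. The lower genes were AT3G44970 (-1.53) and AT3G01345 (-8.17). AT3G01345 had 2953 and 1119 reads in Col-0 and between 2 and 18 in the transgenic libraries, 118 against 0.36 CPM scaled by gene reads alone, a ratio of 327 (244 to 449, counting error only), while its neighbours AT3G01340, AT3G01350 and AT3G01360 had ratios of 1.0 (0.9 to 1.0), 0.6 (0.4 to 0.9, from 44 and 258 reads) and 0.9 (0.8 to 1.0).

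At 75 mM cell wall families had medians above 0 over both controls and smaller ones over the empty vector line, as the root markers did (0.98 in T31-5 and 1.13 in T43-11 over both controls, 0.45 and 0.69 over the empty vector line). Over both controls, 43 extensin-like genes had a median log2 ratio of 0.52 in T31-5 and 0.27 in T43-11, 58 class III peroxidase genes 0.44 and 0.51, 24 expansin genes 0.38 and 0.41, and 43 arabinogalactan protein genes 0.28 and 0.16. Over the empty vector line alone these medians were 0.13 and 0.11, 0.14 and 0.17, 0.05 and 0.07, and 0.06 and -0.02. Among random lists these lay at percentiles of 100 and 100 for extensin-like genes and 100 and 100 for peroxidases. They were 88.6 and 95.6 for expansins and 98.6 and 28.5 for arabinogalactan proteins. Random lists take no account of genes that are regulated together or of copies that share reads. Extensin and peroxidase genes were already among the DESeq2 calls, so these percentiles are no independent support. The 73 chloroplast-encoded genes had -0.17 and -0.21 over both controls and -0.06 and -0.11 over the empty vector line (percentiles 9.98 and 0.69).

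A lower hypoxia response in the Col-0 samples was tested as a hypothesis for the anaerobic genes, on 8 other genes of the response (SUS1, PCO1, PCO2, LBD41, HRA1, HRE1, HRE2 and PDC2). Their median over Col-0 lay above the percentile of random lists set beforehand in 6 of 6 transgenic libraries, at 0.41 and 1.14 log2 in the empty vector line (0 and 75 mM), 0.33 and 1.25 in T31-5 and 0.68 and 1.11 in T43-11, with percentiles of 99.6 to 100. All 8 were higher in 5 of these libraries and 7 in T43-11 at 0 mM, where HRA1 was lower. The 8 genes belong to the same response as those noticed first, and the 6 libraries share the Col-0 libraries. Random lists also take no account of genes that are regulated together. The result therefore extends the first observation and is no independent test of it. The values are consistent with a lower hypoxia response in the Col-0 samples. Whether this lies in the genotype or in how the Col-0 plants were grown or taken cannot be seen with 1 Col-0 library per salt level, and root markers, which were also higher in the empty vector line than in Col-0 (0.32 and 1.04), may contribute.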
